A study of Homo sapiens with 2 samples.

How the data were processed

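Gene expression was measured in 2 cultures of Ca9-22, a human oral carcinoma cell line: the line as obtained, with the genotype given as wild type, and a derivative whose genotype is given as SLPI-deficient. Per the labels' protocols, both were grown in the same serum-containing medium, total RNA was extracted with a column kit, and biotin-labelled cRNA was made from it by in vitro transcription. Per the series' design text, each RNA was hybridized to 1 Affymetrix array of the U133 Plus 2.0 design, so there were 2 arrays in 2 groups with 1 array each.

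The deposited values were RMA levels, per the submitters' processing notes, and were used as log2 values because they ranged from 2.73 to 14.87 on both arrays together. RMA (robust multi-array average) subtracts background, equalizes the distributions of the arrays and summarizes the probes of a probe set. The software, its version, the background settings and whether both arrays were normalized together are not given in the sources used here. The array medians were 5.56 for wild type and 5.48 for the array labelled SLPI-deficient, and the largest gap between their ordered values was 0.13. RMA compresses differences of weak probe sets toward 0 and has no detection call, so a floor was set from the data. It also forces the arrays to similar distributions, so that a shift of most transcripts in 1 direction would not be seen.

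Of 54675 probe sets, 41097 had 1 gene symbol in the platform annotation, 1801 had several and were not named, and 11777 were unnamed here. Symbols were updated by Entrez identifier through a RefSeq gene table of assembly GRCh38.p14, which held the identifiers of 41043 of the 41097 probe sets. That table was used for names and for gene order only. After control probe sets were left out, 41091 probe sets covered 19775 genes, and 19356 genes were left without probe sets whose identifier ends in _x_at, which can bind several genes. Each gene was represented by its probe set with the highest mean level.

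The floor was the 95th percentile of the levels of 106 probe sets of 82 olfactory receptor genes, a log2 level of 5.75. A gene counted as measured on an array when it lay above the floor there, and genes measured on neither array were left out. Levels below the floor were raised to it before the difference was taken, always as the array labelled SLPI-deficient minus wild type. For a gene measured on 1 array only, the difference is a bound, written as at least N-fold. Genes were called higher or lower when they were at least 2-fold apart. No p-value was computed, since 1 array per group gives no replicate error. The internal measure of error was the pooled standard deviation of the differences of different probe sets of a gene. It covers disagreement between probe sets on these 2 arrays, not the spread between cultures or clones, and the number of arrays limits the precision.

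Before the data were examined, 38 gene lists were fixed, covering protease inhibitors and proteases, inflammation and interferon, keratinocyte differentiation, adhesion, growth signalling, cell cycle, metabolism, stress responses, glandular genes and markers of other cell types. A list with at least 5 measured members was placed among 10000 random lists of the same size, matched on mean level in 20 bins. It was called apart from them when its median lay below percentile 2.5 or above percentile 97.5, as a description of these 2 arrays. The genes named were also fixed by rule. They were SLPI, PIGR and PI3, up to 4 members of each list with the largest differences of at least 2-fold, the 12 genes each way with the largest differences among genes measured on both arrays, and the 6 genes each way with the largest bounds. For the last 2 sets, all other measured probe sets of the gene had to have the same sign, and provisional symbols and genes that mark sex were skipped. A gene named outside this rule is said to have been chosen after its values were seen.

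The alternatives were intensity-dependent centring, quantile normalization, the mean of all probe sets of a gene, leaving out probe sets ending in _s_at as well as _x_at, a floor at the median of all probe sets, a floor at the 99th percentile of olfactory receptor probe sets, no floor, thresholds of 3-fold and 1.5-fold, and 10 bins for matching. The calculation was tested on simulated data. A copy of the wild type array was simulated with planted differences and normal noise of the standard deviation measured between probe sets of a gene, 0.42, and run on 12287 genes. Of the genes planted at a log2 difference of 2, 100 of 100 were called, and of those planted at 1.5, 94 of 100. Of 12057 unchanged genes, 198 (1.64%) were called 2-fold apart. All planted genes lay over 2 above the floor on the wild type array, so these rates do not cover genes near the floor. With normal noise of a set size, they follow from the planted difference and that size. They check the calculation, not the error of the real arrays, where some probe sets of a gene disagreed far more. The simulation holds no spread between cultures or clones. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and plots used matplotlib 3.10.9.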

Results

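The data were 54675 probe set levels on each of 2 arrays, 1 of wild type Ca9-22 oral carcinoma cells and 1 of Ca9-22 cells labelled SLPI-deficient. The comparison asked which genes are expressed differently when SLPI, secretory leukocyte protease inhibitor, is missing. With 1 array per group no difference has a replicate check, and every value below compares these 2 arrays, not the genotypes. Of 12550 genes measured on at least 1 array, 10671 were measured on both, 1106 on the wild type array only and 773 on the other array only.

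SLPI, the targeted gene, was read by 1 probe set, with log2 levels of 10.41 on the wild type array and 10.20 on the array labelled SLPI-deficient. The difference of -0.21, or 1.15-fold lower, was smaller than the standard deviation of 0.42 between probe sets of a gene. Both levels were far above the floor of 5.75, at percentiles 94.8 and 93.7 of all probe sets. The targeted gene's level therefore did not bear out the label, and the direction of every difference rests on the label alone. Which part of the gene was disrupted is not given in the sources used here. If the probe set lies outside that part, its level checks nothing. PIGR, the polymeric immunoglobulin receptor, read 6.34 and 6.17, a difference of -0.18. Both PIGR levels lay close to the floor, where differences are compressed toward 0. PI3, the elastase inhibitor elafin and a relative of SLPI, was below the floor on the wild type array and at least 2.56-fold higher on the array labelled SLPI-deficient, at 7.10, but the mean over its 2 probe sets was 0.86, under the 2-fold threshold.

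The 2 arrays differed in genes that mark epithelial type. Keratin 5 (KRT5), a basal keratin of stratified squamous epithelium, read 13.72 on the wild type array and was below the floor on the array labelled SLPI-deficient, at least 252-fold lower. S100P, LYZ (lysozyme), TM4SF4, TSPAN8, SPINK1 and LGALS4, of which several are known from glandular and digestive epithelium, were below the floor on the wild type array and at least 323-fold, 283-fold, 246-fold, 212-fold, 201-fold and 162-fold higher on the other. In the opposite direction, CAV1 (caveolin 1) was at least 139-fold lower, BASP1 at least 117-fold, GJA1 (connexin 43) at least 110-fold, IFI16 at least 80.2-fold and ACKR3 at least 73.4-fold. The 3 probe sets of ACKR3 disagreed in size, with differences from -6.20 to -0.39.

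In all, 1658 genes (13.2% of those measured) were at least 2-fold higher and 1801 (14.4%) at least 2-fold lower on the array labelled SLPI-deficient. Of these, 217 and 262 were at least 8-fold apart. Over the measured genes the levels on the 2 arrays correlated with Pearson's r of 0.73 and Spearman's rho of 0.74, and over all 54675 probe sets with r of 0.91, across genes or probe sets, which are not independent replicates. Different probe sets of a gene mostly gave like differences: across 4621 genes with 2 or more probe sets measured on both arrays, the differences of the brightest pair correlated with r of 0.83. Of 1109 such genes at least 2-fold apart by the brightest probe set, 1051 (94.8%) had the same sign in the next, and 729 were at least 2-fold apart in the same direction in both. The threshold of 2-fold, a log2 difference of 1, exceeded 2 such standard deviations (0.85).

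Among genes measured on both arrays, the largest higher values on the array labelled SLPI-deficient were those of GCNT3, a mucin-type glycosyltransferase, at 107-fold, from 6.01 to 12.75. AGR2, a disulfide isomerase of mucus-secreting cells, was 91.9-fold higher, the transcription factor FOXQ1 65.9-fold and LCN2 (lipocalin 2) 65.1-fold. They were followed by CLDN1 (claudin 1), TRNP1, ENC1, GALNT12, TRIB3, SLC12A2, HOXB7 and MLPH, with differences from 4.87 to 4.40. On the wild type array GCNT3 (6.01), FOXQ1 (5.89), CLDN1 (6.02) and HOXB7 (5.95) lay just above the floor. They were below the 99th percentile floor of 6.09, at which their folds would be bounds. For TRNP1 the mean over all probe sets was 2.68, against 4.80 for the brightest. S100A2, a calcium-binding protein of basal keratinocytes, was 153-fold lower, from 14.56 to 7.30. ALDH1A3, a retinaldehyde dehydrogenase, was 103-fold lower, LGALS1 (galectin 1) 90.7-fold, KRT15 57.3-fold, MLLT11 56.0-fold and CSTA (cystatin A) 56.0-fold. CDH3 (P-cadherin), UCA1, IL1B, P3H2, EGFR and CFAP251 were lower with differences from -5.67 to -4.80. The 3 EGFR probe sets ranged from -4.97 to -3.87, whereas the 2 P3H2 probe sets gave -5.00 and -0.09.

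**Figure D1:**
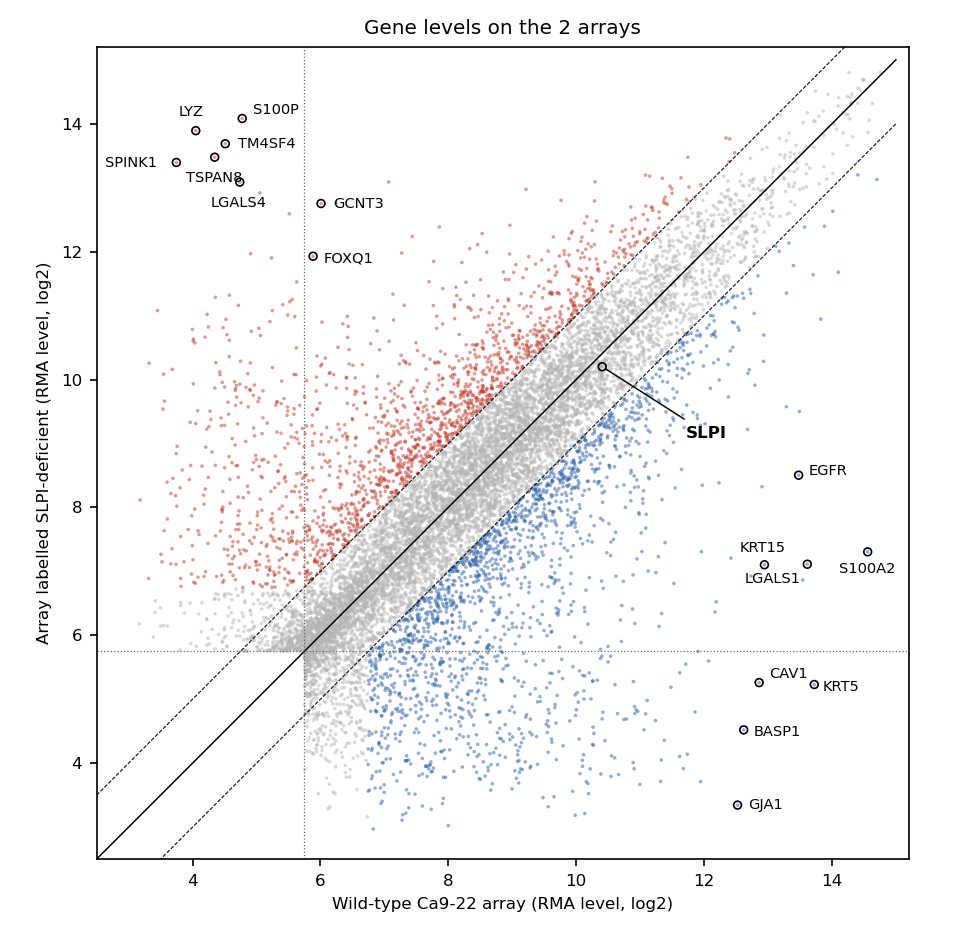
Each point is 1 gene, with its RMA level (log2) on the wild type array on the x axis and on the array labelled SLPI-deficient on the y axis; red and blue mark genes at least 2-fold higher and lower, dashed lines 2-fold and dotted lines the floor of 5.75, and genes that mark sex are not drawn. SLPI lies near the diagonal at 10.41 and 10.20, while KRT5 and S100P lie below the floor on 1 array.

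Of the 38 preset lists, 37 had at least 5 measured members, and 17 lay apart from matched random lists, 12 lower and 5 higher, where 1.85 would do so by chance. Basal keratinocyte and hemidesmosome genes were lower on the array labelled SLPI-deficient: 14 of 24 measured members were at least 2-fold lower, 1 higher and 9 neither, with a median difference of -1.46 (percentile 0 of the random lists). KRT5 and KRT15 led the list, and the desmosomal cadherins DSG3 and DSC3 were at least 53.3-fold and 35.4-fold lower. Of 18 cornified envelope and late differentiation genes, 8 were lower, 1 higher and 9 neither (median -0.65, percentile 0.42). KRT13, a keratin of oral mucosa, was at least 36.5-fold lower, DMKN at least 14.3-fold and SPRR1B at least 5.46-fold, while OVOL1 was 4.12-fold higher. Without a floor the cornified list's median was -0.06 and no longer apart.

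Genes of glandular epithelium were higher on the same array. Of 17 measured mucin and glandular secretory genes, 8 were higher, 1 lower and 8 neither (median 0.87, percentile 99.98), with AGR2 at 91.9-fold, TMC5 at least 36.6-fold, MUC13 at 17.1-fold and MUC20 at least 17.1-fold. Of 5 measured stress and simple epithelial keratins, 3 were higher, 1 lower and 1 neither (median 1.16, percentile 99.46). KRT20, a keratin of intestinal and urothelial epithelium, was at least 144-fold higher and KRT80 7.52-fold higher, while KRT19, high on both arrays at 13.57 and 12.38, was 2.28-fold lower. KRT7 was 2.23-fold higher by its brightest probe set, but its other probe set gave -0.018, and with _s_at probe sets left out the list's median was also -0.018. With the mean of all probe sets KRT19 read -0.77 and the list, at 0.57 (percentile 93.2), was not apart.

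Epithelial junction genes went both ways, with 13 of 35 higher, 6 lower and 16 neither (median 0.33, percentile 95.6). The claudins CLDN3 and CLDN1 were at least 46.5-fold and 29.3-fold higher, and CDH3 and PKP1 50.8-fold and at least 20.9-fold lower. Mesenchymal genes were lower, with 10 of 21 lower, 1 higher and 10 neither (median -0.90, percentile 0). SNAI2, a transcription factor of epithelial-mesenchymal transition, was at least 28.0-fold lower, TGFBI 13.1-fold, AXL at least 9.81-fold and MYL9 at least 15.3-fold, although the other probe set of AXL read -0.84 and that of MYL9 -0.68. Of 26 integrin, laminin and matrix adhesion genes, 12 were lower, 4 higher and 10 neither (median -0.91, percentile 0). CAV1 and CAV2, the caveolins, led this list, with CAV2 25.1-fold lower. The basement membrane collagens COL4A1 and COL4A5 were at least 20.8-fold and 20.4-fold lower, with -0.36 for COL4A5 without its _s_at probe set. TGF-beta targets had 10 of 26 members lower, 5 higher and 11 neither (median -0.46, percentile 0.52), with CCN1 8.96-fold lower, ID3 at least 8.42-fold lower and ID2 18.4-fold higher. Their median was 0.054 without _s_at probe sets. On the same array the glandular list's median was 0.87, and 4 of 5 measured fibroblast markers were lower (median -2.07, percentile 0.24). Whether the adhesion and mesenchymal differences go with epithelial type or with SLPI cannot be told apart on these 2 arrays.

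**Figure D2:**
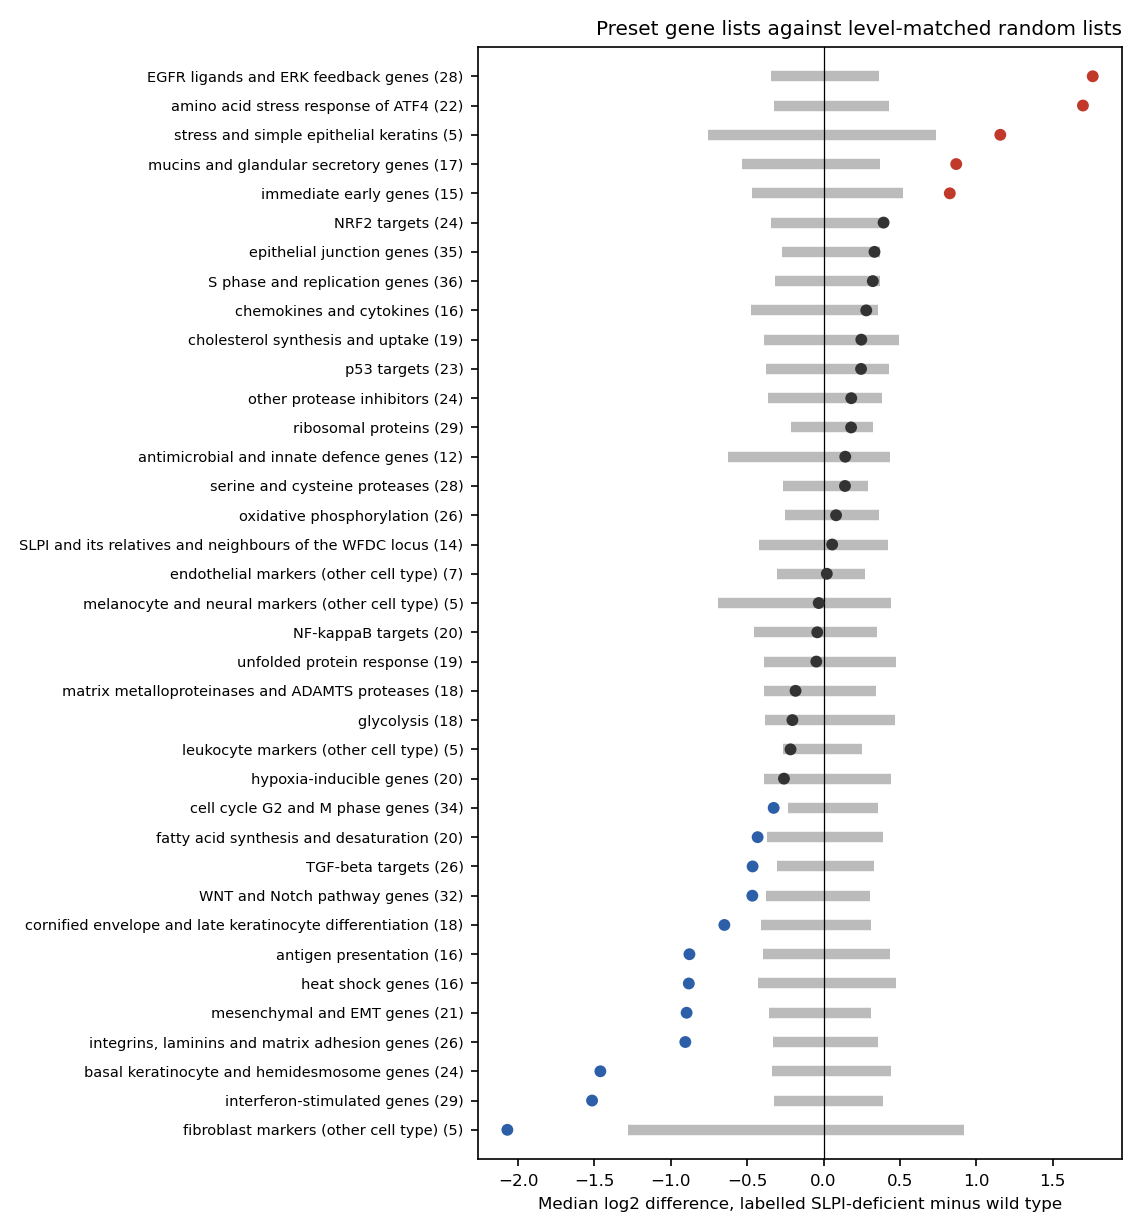
Each dot is the median log2 difference (array labelled SLPI-deficient minus wild type) of 1 of 37 preset lists, with the number of measured members in parentheses, and each grey bar spans the middle 95% of 10000 level-matched random lists. The 5 red and 12 blue lists lie outside their bars, from 1.76 for EGFR ligands and ERK feedback genes to -2.07 for the 5 fibroblast markers.

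Interferon-stimulated genes were lower on the array labelled SLPI-deficient, with 19 of 29 lower, 2 higher and 8 neither (median -1.52, percentile 0). IFI44 was 26.3-fold lower, DDX60 17.4-fold, IFI44L at least 12.4-fold and IFI6 10.7-fold, and IFI44 read -1.50 without its _s_at probe set. Antigen presentation genes had 8 of 16 members lower, 1 higher and 7 neither (median -0.88, percentile 0.02). The immunoproteasome subunit PSMB9 was 21.9-fold lower, NLRC5 at least 6.93-fold and HLA-DMB 6.22-fold, while the peptidase ERAP2 was at least 13.9-fold higher. The glandular list was higher on this array, with a median of 0.87. A link between it and the interferon and antigen presentation lists was not tested, and neither can be assigned to SLPI.

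NF-kappaB targets were not apart, with 3 of 20 higher, 4 lower and 13 neither (median -0.04, percentile 47.5). NFKBIZ was 13.7-fold and TNFAIP2 2.73-fold higher, REL 4.72-fold and TNFAIP3 at least 3.53-fold lower. Of 16 chemokines and cytokines, 4 were lower, 1 higher and 11 neither. Their median of 0.28 (percentile 94.2) and mean of -0.55 differed in sign, with the interleukins IL1B and IL1A 35.7-fold and at least 35.5-fold lower, TNFSF10 14.4-fold lower and TNFSF15 at least 10.4-fold higher. Antimicrobial genes had 3 of 12 members higher, 3 lower and 6 neither (median 0.14, percentile 77.9), with LYZ, LCN2 and DEFB1 higher, the last at least 4.36-fold, and TLR5 at least 3.57-fold lower. This list was apart without _s_at probe sets (median 0.57, percentile 98.3).

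The protease and inhibitor lists closest to SLPI did not lie apart in the main setting, but 3 of the 4 did under 1 alternative each. Among the WFDC locus genes, 4 of 14 were higher, 0 lower and 10 neither (median 0.06, percentile 59.7), with PABPC1L 3.81-fold, WFDC2 3.07-fold and SYS1 2.57-fold higher besides PI3. SYS1 read 0.98 as the mean of its probe sets. Other protease inhibitors had 8 of 24 members higher, 9 lower and 7 neither, with a median of 0.18 (percentile 81.6) and a mean of -0.31, and were apart without _s_at probe sets (median 0.40, percentile 97.8). CSTA, SERPINB13 and SERPINB3 were 56.0-fold, at least 47.6-fold and at least 14.1-fold lower, and TFPI at least 38.6-fold higher. The 5 TFPI probe sets ranged from 0.83 to 5.27. Of 18 matrix metalloproteinases and ADAMTS proteases, 4 were higher, 5 lower and 9 neither (median -0.18, percentile 14.8). Without _s_at probe sets this list was apart, with 6 of 14 lower, 2 higher and a median of -0.75 (percentile 0.28). The collagenases MMP1 and MMP13 were at least 60.9-fold and 45.0-fold lower and MMP10 at least 23.0-fold lower, while MMP7 (matrilysin) was at least 33.5-fold higher. Serine and cysteine proteases had 8 of 28 members higher, 8 lower and 12 neither (median 0.14, percentile 83.6), with CTSH at least 44.4-fold and KLK6 10.5-fold higher and KLK8 22.1-fold and KLK5 at least 13.8-fold lower. KLK8 read -2.47 without its _s_at probe set, and the list was apart with the floor at the 99th percentile (median 0.45, percentile 98.6).

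EGFR ligands and ERK feedback genes were higher on the array labelled SLPI-deficient, with 18 of 28 higher, 2 lower and 8 neither (median 1.76, percentile 100). The ligand EREG was at least 42.9-fold higher, and the ERK-responsive transcription factors ETV4 and ETV5 were 11.3-fold and 9.69-fold higher, whereas the receptor EGFR itself was 31.4-fold lower. The mean over the EREG probe sets was 3.10, against 5.42 for the brightest. Immediate early genes had 6 of 15 members higher, 1 lower and 8 neither (median 0.83, percentile 99.85), among them MAFF at 18.4-fold, KLF6 at 5.90-fold, FOS at 5.81-fold and ATF3 at 5.49-fold. Genes of the ATF4 amino acid stress response were higher, with 17 of 22 higher, 3 lower and 2 neither (median 1.70, percentile 100). TRIB3 was 23.1-fold, the asparagine synthetase ASNS 13.5-fold, NUPR1 12.4-fold and DDIT3 (CHOP) 8.33-fold higher. The glandular list was also higher on this array, with a median of 0.87. Whether the differences of these lists go with epithelial type or with SLPI was not tested.

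**Figure D3:**
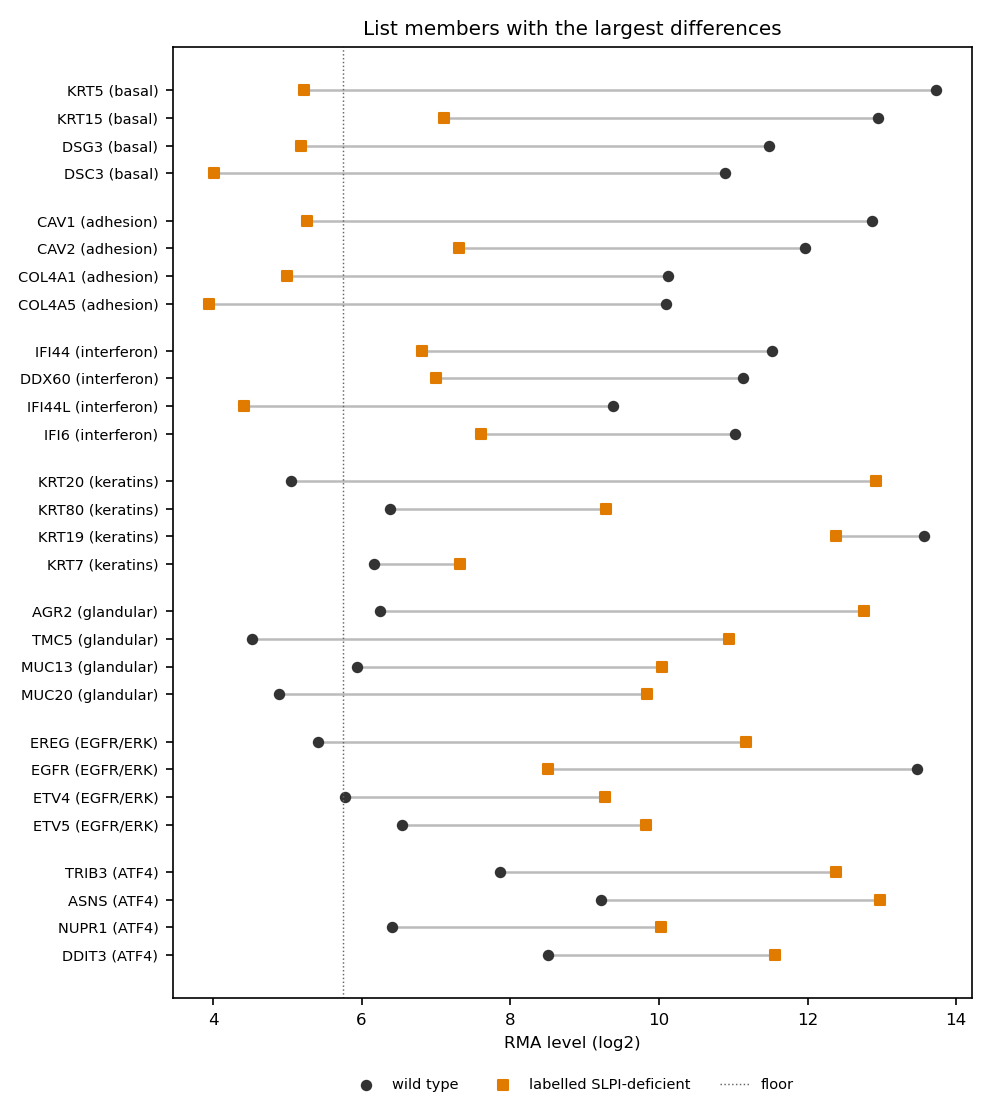
For 7 preset lists that lay apart, the 4 members with the largest differences are drawn with their RMA level (log2) on the wild type array (black circles) and on the array labelled SLPI-deficient (orange squares); the dotted line is the floor of 5.75. KRT5 lay at 13.72 on the wild type array against 5.23, and KRT20 at 5.05 against 12.92, while KRT19 and EGFR ran against the direction of their lists.

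Heat shock genes were lower, with 7 of 16 lower, 1 higher and 8 neither (median -0.88, percentile 0.01). HSPB8 was at least 22.9-fold lower, CRYAB at least 4.39-fold and DNAJB4 4.19-fold, while HSPB1 was 13.8-fold higher. WNT and Notch pathway genes had 11 of 32 members lower, 6 higher and 15 neither (median -0.47, percentile 0.81), with DKK3 and FZD2 at least 23.1-fold and 10.8-fold lower and a difference of -3.46 for DKK1. DKK3 read -2.30 as the mean of its probe sets, and the other probe set of FZD2 read -0.80. The median was -0.28 and not apart without _s_at probe sets. G2 and M phase genes had a median of -0.33 (percentile 0.77), but 0 of 34 were 2-fold apart, and the list was no longer apart with the mean of all probe sets (-0.24, percentile 2.56) or without _s_at probe sets (-0.36, percentile 2.89). Of 36 S phase genes, 7 were higher, 1 lower and 28 neither (median 0.32, percentile 95.6), with CDC45 8.44-fold, MCM7 3.35-fold and CHEK1 2.88-fold higher and GINS4 7.97-fold lower. With the mean of all probe sets CHEK1 read 0.59 and the S phase list was apart (median 0.39, percentile 98.3). The glandular list's median was 0.87 on the same array, and a link between it and these lists was not tested.

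Fatty acid synthesis genes had 6 of 20 members lower, 1 higher and 13 neither (median -0.43, percentile 1.5), with ACSL5 at least 71.3-fold higher and ELOVL5 at least 58.6-fold, FABP5 15.9-fold and FABP4 at least 11.7-fold lower. That list was not apart under 5 alternatives: intensity-dependent centring (-0.46), quantile normalization (-0.42), the mean of all probe sets (-0.31), no _s_at probe sets (-0.31) and the floor at the 99th percentile (-0.45). Among lists not apart in the main setting, p53 targets had 6 of 23 higher and 3 lower (median 0.25, percentile 86.9), with TP53INP1 at least 7.11-fold lower and CCNG1 5.32-fold higher. NRF2 targets had 7 of 24 higher and 2 lower (median 0.39, percentile 97.4), with AKR1B10 17.5-fold and ABCC3 at least 40.2-fold higher, though ABCC3 read 0.84 without its _s_at probe sets. The NRF2 list was apart with the floor at the 99th percentile (median 0.39, percentile 97.6). Hypoxia-inducible genes had 2 of 20 higher and 6 lower (median -0.26, percentile 8.59), with CA12 at least 29.2-fold higher and BNIP3 at least 11.8-fold lower. Glycolysis genes had 2 of 18 higher and 2 lower (median -0.20, percentile 12), among them PFKFB3 at 3.54-fold lower, and were apart with no floor (median -0.45, percentile 0.92). Cholesterol synthesis genes had 1 of 19 higher, INSIG1, and 2 lower, MSMO1 and SREBF1 (median 0.25, percentile 80.9). Unfolded protein response genes had 3 of 19 higher and 0 lower (median -0.05, percentile 33.3), with XBP1 7.57-fold higher. Oxidative phosphorylation genes had 1 of 26 higher, NDUFV2, and 1 lower, ATP5F1C (median 0.08, percentile 53.2), and 0 of 29 ribosomal protein genes were 2-fold apart (median 0.18, percentile 77.6).

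Markers of other cell types were few above the floor. Of 20 fibroblast markers 5 were measured, and 4 of them, COL1A1, C1R, C1S and FBLN1, were lower on the array labelled SLPI-deficient (median -2.07, percentile 0.24). COL1A1 read 10.13 on the wild type array and was at least 20.9-fold lower, but its 3 probe sets differed in sign. Without a floor the list's median was -0.12 and not apart. Of 5 measured leukocyte markers, LCP1 was at least 37.2-fold and CORO1A 2.27-fold lower (median -0.22, percentile 5.73), and the list was apart without _s_at probe sets (percentile 1.11). Of 7 endothelial markers, ESAM was at least 12.6-fold and ENG 3.21-fold higher (median 0.02, percentile 61.2). Of 5 melanocyte and neural markers, PMEL was 2.75-fold lower (median -0.03, percentile 49.8). Only 2 of 35 cancer-testis antigen genes were measured, LAGE3 and PAGE5, chosen after their values were seen, and 0 were 2-fold apart. With no floor that list had 18 members, 0 of them 2-fold apart, and lay apart (median 0.21, percentile 99.5). Among control probe sets, the 3′ minus 5′ level of ACTB was 0.15 on the wild type array and 0.16 on the other, that of GAPDH -0.11 and -0.18, and the 18 hybridization spike probe sets differed by -0.23 to 0.40. The 3 ACTB control probe sets themselves differed by 0.51 to 0.59 and the 3 of GAPDH by -0.46 to -0.34. The control probe sets named for ISGF3A differed by -2.18 to -1.93, and 1 ribosomal RNA control by -0.72.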

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

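The test of the order of genes for scaling bias, those for mixed cells and for the level of SLPI, and those left open for a change of state and for a disruption that leaves the mRNA in place, were chosen only after the result was seen. No result met the preset rules for outliers or for differences between effects, which need more samples, and 3 patterns are weighed here.

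The first pattern was the breadth of the difference, with 3459 of 12550 genes at least 2-fold apart, and noise of single probe sets is argued against by the correlation of 0.83 between the differences of the 2 brightest probe sets of a gene (mark of noise set beforehand: under 0.3). Scaling or intensity bias is argued against by the 3452 and 3443 genes still 2-fold apart after intensity-dependent centring and quantile normalization, within the 10% set beforehand, although these had little to remove because the deposited distributions already lay within 0.13 of each other. A bias that depends on intensity alone also leaves the genes of an array in order, and 62.4% of the pairs of a higher and a lower gene traded their order between the arrays. These pairs were picked by their differences on the same 2 arrays, so noise would make some of them trade as well. The trading argues only against a bias that acts on intensity alone, without noise. Copy number differences of whole chromosome regions may contribute but are argued against as the main source, since taking off the running median of 51 neighbouring genes lowered the number by 11.4%, where over 50% had been set as the bound. A difference of the cells themselves stays open. The lineage lists that bear on it are weighed under the second pattern, and with 1 array of each kind its cause was not tested.

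The second pattern was the low level of squamous genes such as KRT5 together with the high level of glandular genes such as S100P on the array labelled SLPI-deficient. A mixture of wild type cells with cells of another type is argued against for a wild type share of 10% or more, since 20 of 1037 genes with a wild type level of at least 11 lay at or below the floor on the other array. A candidate explanation is that the RNA came from an intestinal or other glandular line in place of Ca9-22. The intestinal list was written after the genes with the largest differences were seen, so it is not independent of the pattern. It held 41 genes, of which 24 were measured, 11 of them on the wild type array. Those measured only on the other array could only read higher. Of the 24, 12 (50%) were at least 2-fold higher, 2 lower and 10 neither. That share neither passed the written bound of over 50% nor came under 25%. The list's median of 1.15 lay at percentile 100 of the random lists. As the difference itself partly set which genes were counted, this test cannot decide on such a line. A change of state that follows from loss of SLPI in Ca9-22 cells may also give such a pattern, and with 1 array labelled SLPI-deficient it cannot be told apart from a property of 1 clone or from another line.

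The third pattern was the level of SLPI, which was nearly alike on both arrays. A probe set that reads only background is argued against by the level of SLPI on the array labelled SLPI-deficient, 4.45 above the floor. A disruption of SLPI at a part that leaves the mRNA in place could leave the level as it was, and so could a wrong label. The array design has 1 SLPI probe set, so these cannot be told apart here.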

How the results depend on the processing

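The alternatives for the lineage lists described under other observations were chosen only after the result was seen, and all others before. The number of genes at least 2-fold higher was 1290 to 1834 and of those lower 1431 to 2116 over the 7 alternatives in normalization, probe sets and floor, against 1658 and 1801. By construction the threshold moved them more: 818 and 910 genes were 3-fold higher and lower, and 2833 and 2960 were 1.5-fold higher and lower. The difference of SLPI was -0.28 with intensity-dependent centring and -0.27 with quantile normalization. The number of lists apart was 15 to 17, and between 11 (without _x_at and _s_at probe sets) and 17 of the 17 kept their call. Lists that were not apart in the main setting also became apart: 4 without _x_at and _s_at probe sets, 2 with the floor at the 99th percentile, 2 with no floor and 1 with the mean of all probe sets. The simple keratins (intensity-dependent centring, floor at the 99th percentile) and the fibroblast markers (without _x_at and _s_at probe sets) had under 5 measured members there and gave no value. Without those probe sets the median of the simple keratins and the difference of KRT7 both became -0.018, and the median of TGF-beta targets 0.0535; KRT7 is then read by another probe set, and the cause for TGF-beta targets was not tested. Of 171 named genes at least 2-fold apart, 24 had a log2 difference over 1.5 times apart from the main one under an alternative other than no floor, each with the mean of all probe sets or without _s_at probe sets. They include TFPI (3.38), ERAP2 (2.31), TP53INP1 (-1.62), DLL1 (-2.22), MUC20 (2.5), ENG (1.04), TFAP2C (-2.15) and SOX7 (-2.5), given here as means of all probe sets. Among the 171, 11 came under 2-fold, HK2 (0.77) and TPPP3 (0.76) among them. The standard deviation between probe sets of a gene was 0.39 to 0.43. Of the comparisons of a list median with an alternative, 304 kept their call, 22 did not and 2 changed sign, and of those of single genes 1030 moved by less than that standard deviation, 130 by more and 1 changed sign. Signal over background limits the genes measured on 1 array only, whose differences are bounds that depend on the floor. It also limits genes that lay just above the floor on 1 array, such as FOXQ1 (5.89, wild type) and CFAP251 (5.90, labelled SLPI-deficient).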

Other observations

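The 6 lineage lists below were written after the genes with the largest differences were seen, leaving those genes out, and the windows of neighbouring genes were chosen for description only after the result was seen. Intestinal epithelium genes were higher on the array labelled SLPI-deficient, with 12 of 24 measured members higher, 2 lower and 10 neither (median 1.15, percentile 100). The list held 41 genes, and members above the floor only on the array labelled SLPI-deficient could only read higher. DPP4 and the scaffold protein USH1C were at least 17.6-fold and 16.9-fold higher. The brush border protein villin (VIL1) and the nuclear receptor HNF4G were at least 15.8-fold and 10.6-fold higher. USH1C read 1.99 in place of 4.08 without its _s_at probe set, and the 3 VIL1 probe sets ranged from 0.36 to 3.98. The intestinal regulator CDX1 (6.63 and 6.68) and the goblet cell mucin MUC2 were less than 2-fold apart, and GUCY2C and FXYD3 were lower. These 4 were chosen after their values were seen. Of 22 listed gastric genes 11 were measured, with 5 higher, 1 lower and 5 neither (median 0.87, percentile 99.98). CAPN8 was at least 5.61-fold and ONECUT2 4.52-fold higher, and GKN2 at least 8.84-fold lower. The gastric median was 0.31 and not apart without _s_at probe sets. Of 27 listed liver and pancreas genes 8 were measured (median 0.28, percentile 95.4). APOH, FOXA2 and FOXA3 were at least 24.4-fold, 7.07-fold and 3.29-fold higher. All of these lay below the floor on the wild type array. On that array 4 of the 8 liver and pancreas genes and 7 of the 11 gastric genes were above the floor. The remaining members of both lists could only read higher. The liver and pancreas list was apart with the mean of all probe sets (0.80) and with the floor at the 99th percentile (0.82).

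The list written for squamous genes outside the preset basal list was lower, with 13 of 24 members lower, 4 higher and 7 neither (median -1.03, percentile 0). SOX7, PKP1 and VSNL1 were at least 21.8-fold, 20.9-fold and 19.8-fold lower, while GJB2 (connexin 26) was 10.9-fold higher. SOX7 and VSNL1 are named here as list members, not as markers of squamous epithelium. The other probe set of SOX7 read -0.56, and PKP1 also stood in the preset junction list. Breast and urothelial genes went both ways, with 3 of 7 higher and 3 lower (median -0.11, percentile 40), the lower being TFAP2C, TFAP2A and GATA3. Of 9 airway genes 1, TPPP3, was higher (median 0.10, percentile 77.3). Of the measured members, 3 intestinal, 2 gastric, 1 breast and urothelial and 3 squamous genes also stood in preset lists, and 11 of the 24 intestinal genes were above the floor on the wild type array too. The brightest intestinal genes on the array labelled SLPI-deficient were TSPAN1 at 12.48, against 10.32 on the wild type array, and PLS1 at 11.03, against 10.54, both chosen after their values were seen.

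Differences were shared by neighbouring genes more than in shuffled orders. Over 12515 genes placed in order, the running median of 51 neighbours had a standard deviation of 0.31, and the highest of 100 shuffles had 0.13. The lowest window, centred on ZNF395 and running from TNFRSF10A to ERLIN2, had a median of -1.07, with 28 of 51 genes at least 2-fold lower and 3 higher. The highest, at a chromosome end and ending at ATP12A, had a median of 1.27, with 15 of 26 genes at least 2-fold higher and 0 lower. The largest window median of any shuffle was 0.83 in size.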
